A study of Homo sapiens with 33 samples.

How the data were processed

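RNA was sequenced from 33 cultures of A-375 and UM-UC-3 cells, grouped here by cell line and edited locus as the labels give them. The deposited design text counts 2 unedited controls and its groups sum to fewer samples than it states, while the labels give 3 unedited samples, and the labels were followed. HISAT2, SAMtools, StringTie and DESeq2 with build hg38 are named in the submitters' processing notes, without versions or the order of steps. The annotation, the gene filter, the design formula and the control libraries of each fit are not given in the sources used here. The kit is stranded per the labels' protocols, and whether the counting used the strand is not given in the sources used here.

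The authors deposited 3 tables of DESeq2 output, with 14332 entries for the A-375 total knockout, 14160 for the A-375 long-form knockout and 13310 for the UM-UC-3 total knockout. Their signal column holds the mean over the libraries of a fit of counts divided by DESeq2 size factors, as the authors' header implies. The log2 columns hold the fold change of knockout over control and its standard error, as the authors fitted them. The fold changes equal the statistic times the standard error, and whether the fit shrank them is not given in the sources used here. The score column is the authors' Wald statistic, and the p-value columns hold its 2-sided normal p, the Benjamini-Hochberg adjusted p and a q-value, per the file headers. Recomputed from the deposited columns, the Wald statistics, p-values and adjusted p-values matched closely. The largest difference in adjusted p, 6.98e-05, was in the A-375 total knockout, where 14331 entries had a p and 14330 an adjusted p. No filter on low counts that removed more than this entry enters the adjustment. The tool behind the q-value is not given in the sources used here, and in each deposited table the q-value is a nearly constant multiple of the adjusted p (medians 0.562, 0.753 and 0.405). A spreadsheet had turned 23, 24 and 20 deposited gene names into dates; these genes were tested but not named. The median mean normalized count was 542 in the A-375 total, 1564 in the A-375 long-form and 1369.9 in the UM-UC-3 table, and genes shared by the A-375 tables had 2.85 times the count in the long-form table. Depth per sample is unknown, so the precision of a value is its standard error in the authors' table.

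Before the data were examined, the comparisons, tests, thresholds, 34 gene lists and the rule for named genes were fixed. A gene was called at an adjusted p of the authors under 0.05. Gene lists were tested with limma cameraPR on the deposited Wald statistic over genes with a mean normalized count of at least 10, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The p-values of cameraPR weigh a list's genes against other genes and do not measure how far a list varies between clones. Counts adjusted over the list alone use the deposited p-values of its members. The difference of a gene between tables was tested as the difference of the log2 fold changes over the root of their summed squared errors, with a normal p and Benjamini-Hochberg adjustment over genes with a mean of at least 10 in both tables. The A-375 tables may share controls, in which case this standard error is too large. Overlaps of calls were set against independent lists with a one-sided Fisher's exact test over genes, and against 100 simulated pairs of unchanged knockouts with 2 or 6 shared controls. Control levels were worked out from the mean normalized count, the fold change and the number of libraries, for each number of controls that the labels allow.

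Named genes follow this rule, and some genes that it gives are not reported here: GABPB1, GABPA, GABPB2 and TERT; in each table the 8 called genes each way with the smallest adjusted p, a mean of at least 100 and a log2 change of at least 1; for each list up to 4 members with the smallest adjusted p; the 8 genes each way called in both cell lines; and the 5 each way with the smallest adjusted p for each difference. GABPB1 has separate deposited entries for its forms. Read-through, pseudogene and clone names given by the rule were left out because their reads overlap those of other genes. Places of genes were taken from GENCODE release 29 on hg38, in which 13948 of 14331, 13781 of 14159 and 12967 of 13310 symbols were found.

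Lists were also tested with the trend on transcript length or GC content removed, using the annotation's longest transcripts (length known for 13940 of 14323, 13770 of 14148 and 12966 of 13309 tested genes), after the median of each gene's 50 chromosomal neighbours was removed, and by their median against 10000 random lists matched on mean normalized count. List differences between tables were tested with cameraPR on the z of each gene's difference. The trend removals, the neighbour removal, the use of the q-value and the test of list differences were chosen after the data were seen. Other alternatives were an adjusted p of 0.01 or 0.1, floors on the mean count or the fold change, a Wald test against a log2 change of 0.5, centring on the median, Wald statistics divided by their robust SD, the deposited q-value, rank-based cameraPR, log2 fold changes in cameraPR and a correlation of 0.05. No refit, leave-one-out, replicate block or regrouping was made, since the tables hold no value per library.

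The calls of genes, of gene differences and of gene lists were tested on simulated tables, with 200 changed genes for the first 2. The tests of list differences, overlaps, matched random lists, trend and neighbour removal, motifs and windows were not tested in this way. Simulated unchanged genes had exactly standard normal Wald statistics, and simulated lists had no inter-gene correlation. The deposited Wald statistics were wider (robust SD 1.70, 1.28 and 2.37 in the A-375 total, A-375 long-form and UM-UC-3 tables). The few unchanged genes called therefore follow from the setting and do not give the false calls of the deposited tables. At log2 changes of 0.5, 1 and 2, the A-375 total-knockout setting (14323 genes) recovered 13.4%, 49.3% and 83.3%, with 2 unchanged genes called. The A-375 long-form setting (14148 genes) recovered 23.9%, 56.7% and 89.4%, with 5, and the UM-UC-3 setting (13309 genes) 37.3%, 79.1% and 100%, with 4. For differences, that between the lines (12640 genes) recovered 2.99%, 43.3% and 83.3%, with 2, and that between the A-375 knockouts (13947 genes) 4.48%, 43.3% and 77.3%, with 5. Of 20 lists shifted by 1 unit of the Wald statistic, 80%, 70% and 85% were called in the A-375 total, A-375 long-form and UM-UC-3 settings, and 5%, 5% and 0% at 0.3 units.

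Mitochondrially encoded mRNAs have no entry in any of the 3 tables and were not analysed here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.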

Results

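RNA sequencing was done on 33 libraries of human cancer cells in which GABPB1, a subunit of the transcription factor GABP, had been deleted in part. GABP joins GABPA, an ETS-family protein that binds DNA, to a B subunit, which is GABPB1 or its paralog GABPB2. A long splice form, GABPB1L, carries a leucine zipper that the short form, GABPB1S, lacks. The cells were A-375, a melanoma line (20 libraries), and UM-UC-3, a bladder cancer line (13 libraries). In A-375, 4 libraries came from clones with exons 2 to 9 deleted, 8 from clones with exon 2 deleted and 2 from clones with exon 9, used by the long form, deleted. The A-375 controls were 4 libraries from clones edited at the ROSA26 safe-harbour locus and 2 of unedited cells. In UM-UC-3, 4 libraries came from clones with exons 2 to 9 deleted, 5 from clones with exon 2 deleted, 3 from ROSA26 clones and 1 from unedited cells. The first pair of knockout designs was analysed together as the total knockout (12 libraries from 9 A-375 clones, 9 libraries from 8 UM-UC-3 clones), and the exon 9 deletion as the long-form knockout (2 libraries from 2 A-375 clones).

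The values were fitted log2 fold changes with standard errors, 1 per gene, from 3 tables in which the authors set a knockout against its cell line. No value per library was used here, so the depth of each sample is unknown and the spread between replicates appears only through each standard error. Summed over genes, the mean normalized counts came to 19457299 in the A-375 total-knockout table, 53514594 in the A-375 long-form table and 42400454 in the UM-UC-3 table. The tables are named as knockout over parental, and the series holds 2 parental libraries of A-375 and 1 of UM-UC-3, besides those of ROSA26 clones. The tables do not say which control libraries entered each fit, so each UM-UC-3 value may rest on 1 control library. Several libraries came from the same clone, and whether the fits treated these as independent replicates is not given in the sources used here.

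In A-375 cells, the total knockout asked which transcripts follow the loss of both forms of GABPB1 (chromosome 15, 50275392 to 50355408, hg38). GABPB1L fell by 10.60 ± 0.70 on the log2 scale (SE; adjusted p 1.61e-47) in the authors' deposited table, and GABPB1S changed by -9.81 ± 0.72 (adjusted p 2.76e-38). Both were nearly absent from the knockout. Entries named GABPB1L-DEX2 and GABPB1S-DEX2 were seen almost only in the knockout. They rose by 13.61 ± 1.96 (adjusted p 3.74e-09) and 12.36 ± 1.88 (adjusted p 3.37e-08) in the authors' deposited table. With 1 group near 0, the sizes of these 4 changes have no fold meaning. With 2 controls assumed, the implied level in the knockout was 718 normalized counts for GABPB1L-DEX2 and 300 for GABPB1S-DEX2 (923 and 386 with 6). In the controls it was 909 for GABPB1L and 525 for GABPB1S (390 and 226 with 6). RNA named as GABPB1 was therefore still present in the knockout, and only the entries GABPB1L and GABPB1S were lost. The partner subunit GABPA rose by 0.81 ± 0.22 (adjusted p 0.00508) in the authors' deposited table, and the paralog GABPB2 rose by 1.81 ± 0.32 (adjusted p 6.05e-06). TERT, the catalytic subunit of telomerase and a GABP target where its promoter is mutated, fell by 5.16 ± 1.69 on the log2 scale (adjusted p 0.0287) in the authors' deposited table.

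Of 14329 genes tested in this table, 1549 (10.8%) passed an adjusted p of 0.05, 726 higher and 823 lower, and 390 and 336 of these changed at least 2-fold. After centring, 907 were higher and 647 lower. Among the genes with the clearest rise were CD163L1, a scavenger-receptor family member (4.24 ± 0.60, adjusted p 1.77e-09), and the prostaglandin synthase PTGS2 (5.52 ± 0.82, adjusted p 1.57e-08), both in the authors' deposited table. HYDIN, a cilium protein, rose by 4.23 ± 0.64 (adjusted p 2.5e-08) and the LIM-domain cofactor FHL2 by 1.53 ± 0.25 (adjusted p 2.98e-07) in the authors' deposited table. GALNT18, a glycosyltransferase, rose by 1.73 ± 0.29 (adjusted p 6.6e-07) in the authors' deposited table. The clearest falls in the authors' deposited table included RMND5B, part of a ubiquitin ligase (-3.43 ± 0.33, adjusted p 7.17e-22), and the mitotic kinase NEK9 (-2.74 ± 0.27, adjusted p 7.93e-21). EMILIN2, an extracellular matrix protein (-4.50 ± 0.45, adjusted p 3.25e-20), and the deubiquitinase USP11 (-2.14 ± 0.23, adjusted p 5.77e-18) fell in the authors' deposited table. So did the kinase MAP2K5 (-2.15 ± 0.27, adjusted p 1.24e-12 in the authors' deposited table). FLG, which encodes the epidermal protein filaggrin, fell by 2.71 ± 0.37 on the log2 scale (adjusted p 1.81e-10) in the authors' deposited table. Its antisense neighbour FLG-AS1 changed by -2.91 ± 0.26 (adjusted p 5.06e-25) in the authors' deposited table. FLG-AS1 spans FLG and its neighbours HRNR and FLG2 from the opposite strand. The strand setting of the counting is not stated, so FLG-AS1 and these genes may share reads, and their values are uncertain.

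Several groups of genes rose in the A-375 total knockout. Of 23 measured targets of the tumour suppressor p53, 17 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median log2 change of 0.88 (cameraPR adjusted p 7.00e-15). CDKN1A, an inhibitor of cell-cycle kinases, rose by 1.69 ± 0.29 (adjusted p 2.03e-06) in the authors' deposited table. The DNA repair gene DDB2 (0.80 ± 0.15, adjusted p 1.46e-05), the kinase PLK3 (1.25 ± 0.25, adjusted p 5.06e-05) and FDXR (1.19 ± 0.26, adjusted p 0.000453) rose too in the authors' deposited table. Cytosolic ribosomal proteins, the protein part of the translating ribosome, had 13 of 77 members higher and 0 lower (24 and 0 adjusted over the list alone). Their median was 0.39 (adjusted p 2.16e-14). In the authors' deposited table, RPS21 rose by 0.79 ± 0.22 (adjusted p 0.00916), RPS27 by 1.11 ± 0.32 (adjusted p 0.0106) and RPL36 by 0.54 ± 0.17 (adjusted p 0.0198). Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 7 of 11 members higher and 0 lower (8 and 0 adjusted over the list alone). Their median was 2.23 (adjusted p 4.68e-08). HIST2H2BE (2.76 ± 0.48, adjusted p 3.09e-06), HIST1H1C (2.52 ± 0.55, adjusted p 0.000344) and HIST1H2BK (2.23 ± 0.48, adjusted p 0.000281) were among them in the authors' deposited table. Each is uncertain because near-identical copies can share reads. The histone list was fixed as a check on polyadenylation, and a difference between libraries in how RNA was captured was not tested, for want of values per library.

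Genes of antigen presentation, which display peptides to T cells, had 7 of 19 members higher and 0 lower (9 and 0 adjusted over the list alone; median 0.92, adjusted p 3.06e-06). HLA-E (2.87 ± 0.85, adjusted p 0.0131) and HLA-B (1.85 ± 0.55, adjusted p 0.0144) rose in the authors' deposited table. These paralogs can share reads. Autophagy and lysosome genes had 7 of 30 members higher and 0 lower (13 and 1 adjusted over the list alone). Their median was 0.39 (adjusted p 5.12e-06). MAP1LC3B, an autophagosome protein, rose by 0.80 ± 0.15 (adjusted p 2.43e-05), the cargo receptor SQSTM1 by 1.24 ± 0.32 (adjusted p 0.00275) and GABARAPL1 by 0.89 ± 0.27 (adjusted p 0.018) in the authors' deposited table. The NF-kB and cytokine list had 3 of 17 members higher and 0 lower (4 and 0 adjusted over the list alone; median 0.83, adjusted p 0.00116). These were BIRC3 (1.77 ± 0.53, adjusted p 0.014), TNFAIP3 (1.35 ± 0.44, adjusted p 0.0294) and IL1B (adjusted p 0.0335) in the authors' deposited table. Chaperones of the endoplasmic reticulum moved up as a list (median 0.28, adjusted p 0.00116), a call lost with log2 fold changes in cameraPR (0.165). Of these, 1 of 20 was higher and 0 lower (0 and 0 adjusted over the list alone), P4HB (0.72 ± 0.25, adjusted p 0.0441 in the authors' deposited table). Interferon-stimulated genes had 4 of 31 members higher and 1 lower (6 and 1 adjusted over the list alone; median 0.30, adjusted p 0.04). This call was lost with an inter-gene correlation of 0.05 (0.173), log2 fold changes in cameraPR (0.103) and the trend on transcript length removed (0.0686). In the authors' deposited table the higher ones were IFI35 (0.90 ± 0.26, adjusted p 0.0114), IFI6 (1.24 ± 0.39, adjusted p 0.0229), IRF9 (1.27 ± 0.41, adjusted p 0.0276) and OAS2 (1.12 ± 0.40, adjusted p 0.0475). The lower one was IRF7 (-1.43 ± 0.48, adjusted p 0.0323 in the authors' deposited table). OAS2 was chosen after its values were seen.

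Cell-division genes moved down as lists, with few members past the threshold on their own. Of 39 DNA replication and G1/S genes, 3 were lower and 0 higher (1 and 0 adjusted over the list alone), with a median of -0.59 (adjusted p 0.000328). POLA1, which starts DNA synthesis, fell by 1.12 ± 0.20 on the log2 scale (adjusted p 8.46e-06) in the authors' deposited table. The other 2 calls, POLE2 (-1.47 ± 0.53, adjusted p 0.0478) and MCM3 (-0.94 ± 0.34, adjusted p 0.0485) in the authors' deposited table, were lost when the table was centred on its median. Mitotic genes had 1 of 40 members lower and 0 higher (0 and 0 adjusted over the list alone), a median of -0.98 and an adjusted p of 6.68e-05. The call was the spindle protein CKAP2 (-1.11 ± 0.37, adjusted p 0.0319 in the authors' deposited table). Homologous recombination and Fanconi genes, which repair double-strand breaks and crosslinks, had 3 of 28 members lower and 0 higher (4 and 0 adjusted over the list alone; median -0.71, adjusted p 4.11e-05). CHEK2 (-1.31 ± 0.32, adjusted p 0.00177), FANCL (-0.79 ± 0.20, adjusted p 0.00225) and FANCI (-1.07 ± 0.28, adjusted p 0.00319) fell in the authors' deposited table.

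Respiratory complex I, which takes electrons from NADH, shifted up slightly (median 0.17, adjusted p 0.0171). It had 3 of 35 members higher and 0 lower (3 and 1 adjusted over the list alone). NDUFA8 (0.39 ± 0.11, adjusted p 0.0105), NDUFB10 (0.53 ± 0.17, adjusted p 0.0225) and NDUFV2 (0.30 ± 0.10, adjusted p 0.0291) rose in the authors' deposited table. Complexes II to IV had 1 of 25 members higher and 0 lower (1 and 0 adjusted over the list alone; median 0.16, adjusted p 0.04). The proteasome had 1 of 31 higher and 0 lower (0 and 0 adjusted over the list alone; median 0.12, adjusted p 0.0194). The members called were COX7A2L (0.44 ± 0.13, adjusted p 0.0151) and PSMB7 (0.32 ± 0.11, adjusted p 0.0351) in the authors' deposited table. The lists of complex I, complexes II to IV and the proteasome lost their calls with an inter-gene correlation of 0.05 (adjusted p 0.129, 0.167 and 0.129), with the trend on transcript length removed (0.250, 0.268 and 0.160) and with log2 fold changes in cameraPR (0.495, 0.519 and 0.602). The proteasome also lost its call against matched random lists (0.0738). The telomere list was not called (median -0.23, adjusted p 0.0635), with 4 of 20 members lower and 0 higher (4 and 0 adjusted over the list alone). It passed with the trend on transcript length (0.0295) or GC content (0.0425) or the chromosomal neighbours (0.0266) removed, and by log2 fold changes or ranks in cameraPR, but not against matched random lists (0.180). ACD, a protein of the telomere cap, fell by 0.65 ± 0.21 on the log2 scale (adjusted p 0.0285) in the authors' deposited table. The others were TERT, TERF1 (-0.58 ± 0.20, adjusted p 0.0361) and NHP2 (-0.58 ± 0.20, adjusted p 0.0401) in the authors' deposited table. TERF1 and NHP2 lost their calls after centring. TFB1M, a mitochondrial rRNA methyltransferase, fell by 0.90 ± 0.20 on the log2 scale (adjusted p 0.000603) in the authors' deposited table.

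In UM-UC-3 cells, the same deletions asked the same question in another cancer type. GABPB1L fell by 12.60 ± 0.71 on the log2 scale (adjusted p 1.32e-66) and GABPB1S changed by -9.86 ± 2.70 (adjusted p 0.00191) in the authors' deposited table. GABPB1L-DEX2 rose by 11.82 ± 1.46 (adjusted p 1.98e-13) and GABPB1S-DEX2 by 10.15 ± 1.62 (adjusted p 2.23e-08) in the authors' deposited table, again with 1 group near 0. GABPA rose by 1.43 ± 0.19 (adjusted p 6.25e-12) and GABPB2 by 2.49 ± 0.20 (adjusted p 5.22e-32) in the authors' deposited table. TERT fell by 1.77 ± 0.63 on the log2 scale (adjusted p 0.0208) in the authors' deposited table.

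**Figure D1:**
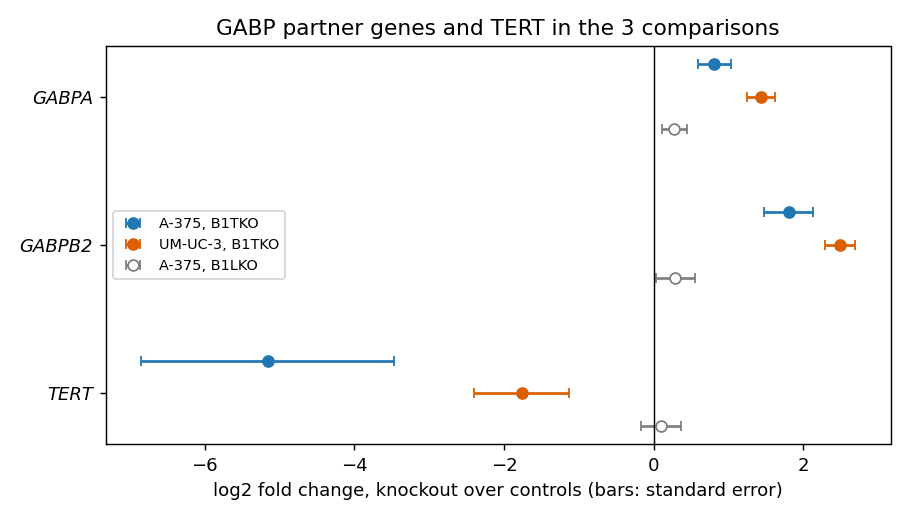
Log2 fold change with its standard error of GABPA, GABPB2 and TERT in each of the 3 comparisons of the authors' deposited tables; filled points were called at an adjusted p of 0.05 and open grey points were not. GABPA and GABPB2 lie above 0 and TERT below 0 in both total knockouts, and none of the 3 genes was called in the long-form knockout.

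Of 13310 genes tested in UM-UC-3, 4145 (31.1%) passed, 2260 higher and 1885 lower, of which 616 and 279 changed at least 2-fold. After centring, 2037 were higher and 2106 lower. These calls, and every difference from A-375, may rest on 1 parental library. WIPI1, a protein of early autophagosomes, rose by 1.85 ± 0.14 (adjusted p 4.37e-37) and the ribonuclease RNASE4 by 1.57 ± 0.17 (adjusted p 4.35e-18) in the authors' deposited table. SBSN, an epidermal secreted protein (3.12 ± 0.34, adjusted p 1.5e-17), and the mitochondrial dehydrogenase ALDH6A1 (1.36 ± 0.15, adjusted p 3.55e-17) also rose in the authors' deposited table, as did the oestrogen-responsive gene GREB1 (2.88 ± 0.32, adjusted p 6.1e-17). ANTXR1, an anthrax toxin receptor that binds collagen, changed by -4.86 ± 0.28 (adjusted p 2.17e-65) and USP11 by -2.33 ± 0.16 (adjusted p 1.9e-43) in the authors' deposited table. Lower too in the authors' deposited table were C22orf46 (-1.94 ± 0.18, adjusted p 1.36e-24), the microtubule-associated RMDN1 (-1.38 ± 0.14, adjusted p 1.37e-20) and the centriolar satellite protein CCDC14 (-2.69 ± 0.27, adjusted p 3.43e-20). The glucosylceramidase GBA2 (-1.72 ± 0.17, adjusted p 6.02e-20) and mitochondrial thioredoxin TXN2 (-1.06 ± 0.11, adjusted p 4.1e-19) were lower as well in the authors' deposited table.

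DNA replication and G1/S genes formed the list with the smallest p in UM-UC-3 (median -0.87, adjusted p 1.25e-16). Of 39, 31 were lower and 0 higher (31 and 0 adjusted over the list alone). RFC4, a clamp loader (-0.87 ± 0.08, adjusted p 6.02e-24), thymidylate synthase TYMS (-2.35 ± 0.25, adjusted p 2.69e-18) and the polymerase subunit POLD1 (-0.85 ± 0.15, adjusted p 5.37e-07) were lower in the authors' deposited table. Repair genes of homologous recombination and the Fanconi pathway had 11 of 28 lower and 0 higher (16 and 0 adjusted over the list alone; median -0.51, adjusted p 2.05e-05). FANCA (-1.07 ± 0.16, adjusted p 1.41e-09) and FANCL (-1.18 ± 0.20, adjusted p 7.88e-08) fell in the authors' deposited table. Mitotic genes had 12 of 40 lower and 0 higher (12 and 0 adjusted over the list alone; median -0.37, adjusted p 0.000122). AURKB (-0.81 ± 0.24, adjusted p 0.00382) and TPX2 (-0.56 ± 0.17, adjusted p 0.00425) fell in the authors' deposited table.

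Genes of mitochondrial respiration fell in UM-UC-3. Complex I had 17 of 37 members lower and 0 higher (19 and 0 adjusted over the list alone; median -0.37, adjusted p 2.98e-06). Complexes II to IV had 13 of 25 lower and 0 higher (17 and 0; median -0.44, adjusted p 4.69e-05). The ATP synthase had 12 of 16 lower and 0 higher (14 and 0; median -0.42, adjusted p 3.15e-06). NDUFC2 (-0.75 ± 0.14, adjusted p 3.7e-06) and NDUFB6 (-0.66 ± 0.13, adjusted p 9.7e-06) of complex I fell in the authors' deposited table. UQCRQ (-0.78 ± 0.18, adjusted p 0.000285), COX6A1 (-0.75 ± 0.18, adjusted p 0.000336) and ATP5J (-0.69 ± 0.13, adjusted p 2.28e-06) fell as well in the authors' deposited table. The mitochondrial ribosome, which translates the organelle's own mRNAs, had 24 of 78 members lower and 2 higher (29 and 3 adjusted over the list alone; median -0.26, adjusted p 2.71e-06). MRPL16 stood at -0.98 ± 0.13 (adjusted p 8.67e-12) and MRPL33 at -1.12 ± 0.16 (adjusted p 3.43e-10) in the authors' deposited table. Genes of mitochondrial DNA expression and import had 11 of 34 lower and 4 higher (12 and 4 adjusted over the list alone; median -0.14, adjusted p 0.032). This call was lost with an inter-gene correlation of 0.05 (0.173), log2 fold changes in cameraPR (0.232), the trend on transcript length removed (0.118) and against matched random lists (0.149). LRPPRC, which stabilises mitochondrial mRNAs, rose by 0.43 ± 0.07 (adjusted p 3.31e-08) in the authors' deposited table.

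Protein synthesis and degradation genes moved down as well in UM-UC-3. The proteasome had 18 of 31 members lower and 0 higher (19 and 0 adjusted over the list alone; median -0.30, adjusted p 2.52e-07). PSMC2 stood at -0.83 ± 0.12 (adjusted p 1.57e-09) and PSMB1 at -0.76 ± 0.12 (adjusted p 4.47e-09) in the authors' deposited table. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, had 7 of 20 lower and 1 higher (8 and 1 adjusted over the list alone; median -0.22, adjusted p 0.0063). This list lost its call against matched random lists (0.240) and with log2 fold changes in cameraPR (0.228). QARS (-0.60 ± 0.09, adjusted p 1.7e-10) and MARS (-0.89 ± 0.15, adjusted p 2.48e-07) fell in the authors' deposited table. DARS, chosen after its values were seen, rose by 0.46 ± 0.12 (adjusted p 0.000605) in the authors' deposited table. Cytosolic ribosomal proteins had 2 of 77 lower and 0 higher (0 and 0 adjusted over the list alone; median -0.27, adjusted p 0.000637). The calls were RPL15 (-0.37 ± 0.13, adjusted p 0.0135) and RPL6 (-0.40 ± 0.15, adjusted p 0.029) in the authors' deposited table. This list's call ended with the trend on transcript length removed (median -0.09, adjusted p 0.147) and with an inter-gene correlation of 0.05 (adjusted p 0.0604).

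Genes that rose in UM-UC-3 included 13 of 20 chaperones of the endoplasmic reticulum, which fold secreted proteins (0 lower; 14 and 0 adjusted over the list alone; median 0.60, adjusted p 3.15e-06). DNAJB9 (2.09 ± 0.27, adjusted p 3.26e-12), HSPA5 (1.25 ± 0.26, adjusted p 2.19e-05) and SEL1L (1.03 ± 0.19, adjusted p 1.56e-06) rose in the authors' deposited table. Autophagy and lysosome genes had 11 of 30 higher and 1 lower (12 and 1 adjusted over the list alone; median 0.25, adjusted p 0.000372). This call was lost with log2 fold changes in cameraPR (0.232). Among them were GABARAPL1 (1.34 ± 0.19, adjusted p 1.14e-10) and LAMP2 (0.83 ± 0.13, adjusted p 3.99e-08) in the authors' deposited table. The 1 lower was GABARAPL2 (-0.66 ± 0.17, adjusted p 0.000875 in the authors' deposited table), chosen after its values were seen. Interferon-stimulated genes had 9 of 24 higher and 1 lower (10 and 2 adjusted over the list alone; median 0.74, adjusted p 0.032). IRF9 (1.12 ± 0.23, adjusted p 3.23e-05) and IFI6 (1.19 ± 0.32, adjusted p 0.00158) rose in the authors' deposited table. Histone genes had 5 of 10 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.77, adjusted p 0.0285). HIST2H2BE stood at 1.64 ± 0.29 (adjusted p 5.53e-07) and HIST1H1E, chosen after its values were seen, at -1.34 ± 0.52 (adjusted p 0.0341) in the authors' deposited table. Of 5 measured blood cell markers 3 were higher and 0 lower (3 and 0 adjusted over the list alone; median 1.17, adjusted p 0.0285). They were the lysosomal protein CD68 (1.29 ± 0.14, adjusted p 1e-16), ITGAX (1.32 ± 0.35, adjusted p 0.00113) and CSF1R (1.17 ± 0.37, adjusted p 0.0083) in the authors' deposited table. With an inter-gene correlation of 0.05 the blood marker (adjusted p 0.0525), interferon (0.142) and histone (0.0652) lists lost their calls. The blood marker and histone calls were also lost with log2 fold changes (0.217 and 0.107) and with ranks (0.169 and 0.0501) in cameraPR, and the histone call with the chromosomal neighbours removed (0.0525).

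Some genes moved within lists that were not called in UM-UC-3. The p53 targets had 3 of 21 members higher and 1 lower (3 and 1 adjusted over the list alone; median 0.21, adjusted p 0.27). Within the ATF4-driven stress response, which had 5 members higher and 5 lower of 27 (5 and 6 adjusted over the list alone; adjusted p 0.574), DDIT3 rose by 1.98 ± 0.25 (adjusted p 4.91e-13) in the authors' deposited table. The amino acid synthesis genes ASNS (-0.87 ± 0.14, adjusted p 5.74e-08) and PHGDH (-1.04 ± 0.17, adjusted p 2.33e-08) fell in the authors' deposited table. HMOX1, which breaks down haem, rose by 1.61 ± 0.24 (adjusted p 1.29e-09) and HLA-B by 1.53 ± 0.33 (adjusted p 5.23e-05) in the authors' deposited table. The telomerase RNP proteins NHP2 (-0.72 ± 0.14, adjusted p 2.97e-06) and NOP10 (-0.65 ± 0.19, adjusted p 0.0031) fell in the authors' deposited table.

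**Figure D2:**
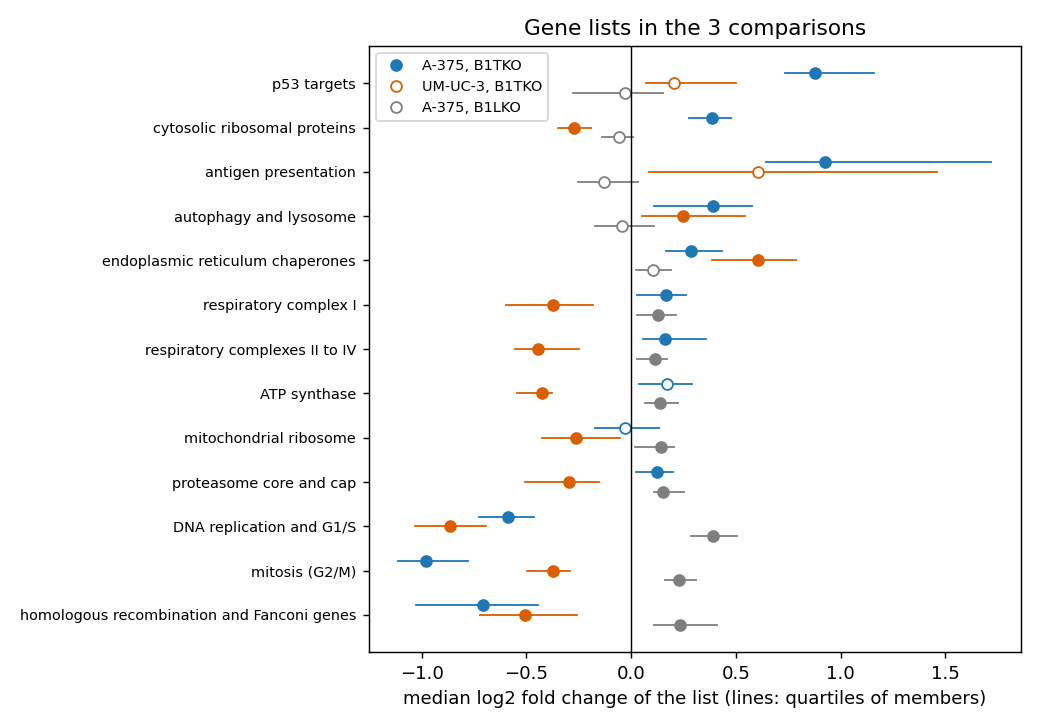
Median log2 fold change of the members of 13 gene lists in the 3 comparisons, with lines from the lower to the upper quartile of the members; filled points mark lists called at an adjusted p of 0.05 and open points lists not called. The p53 list has a median of 0.88 in the A-375 total knockout and 0.21 in UM-UC-3, and the replication list lies below 0 in both total knockouts and at 0.39 in the long-form knockout.

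In A-375 cells, the deletion of exon 9 asked what the loss of the long form does. GABPB1L fell by 12.79 ± 1.47 on the log2 scale (adjusted p 1.78e-14) in the authors' deposited table. GABPB1S rose by 13.95 ± 1.04 (adjusted p 3.55e-37) and GABPB1S-DEX2 fell to near 0 (adjusted p 1.76e-12) in the authors' deposited table. Both went the other way in the total knockout. The control level implied for GABPB1S was 1497.9 normalized counts in the total-knockout table (2 control libraries assumed; 644.8 with 6), scaled for depth, against 0.129 (0.257 with 6) in the long-form table. The name therefore does not mark the same entry in both tables. The short-form entry seen in the controls of the long-form table was GABPB1S-DEX2 (implied level 888 with 2 control libraries, 592 with 6), which fell to near 0. The knockout held the entry named GABPB1S at an implied 2040 counts with 2 control libraries and 4080 with 6, above that control level. What this entry holds is not given, so whether the short form was kept in this knockout is not shown. GABPA (0.28 ± 0.17, adjusted p 0.552), GABPB2 (0.29 ± 0.26, adjusted p 0.695) and TERT (0.10 ± 0.27, adjusted p 0.913) were not called in the authors' deposited table.

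Of 14155 genes tested, 128 (0.904%) passed, 34 higher and 94 lower, of which 11 and 63 changed at least 2-fold. PRPF8, a core protein of the spliceosome, changed by -2.46 ± 0.21 (adjusted p 1.07e-28), and TRO, a cell-adhesion gene, by -5.21 ± 0.87 (adjusted p 6.09e-06) in the authors' deposited table. MYO15B (-1.84 ± 0.31, adjusted p 7.5e-06), the nuclear RNA NEAT1 (-1.35 ± 0.24, adjusted p 3.65e-05) and the phosphatase PTPRK (-2.93 ± 0.54, adjusted p 8.96e-05) fell in the authors' deposited table. CTSK, a lysosomal protease (2.95 ± 0.47, adjusted p 7.46e-07), the RNA-binding protein TAF15 (2.37 ± 0.53, adjusted p 0.00398) and the tumour antigen PRAME (2.16 ± 0.55, adjusted p 0.0173) rose in the authors' deposited table. FLG (-1.55 ± 0.32, adjusted p 0.000626) and its neighbours HRNR (-1.97 ± 0.40, adjusted p 0.000602) and FLG2 (-1.80 ± 0.43, adjusted p 0.00802), which encode related epidermal proteins, fell in the authors' deposited table. HRNR and FLG2 were chosen after their values were seen. FLG-AS1 spans FLG, HRNR and FLG2, and reads may be shared among them. The immediate early genes FOS (-1.73 ± 0.38, adjusted p 0.00336) and IER3 (-1.69 ± 0.36, adjusted p 0.00126) fell in the authors' deposited table. The collagens COL6A1 (-0.66 ± 0.15, adjusted p 0.00615) and COL6A2 (-0.79 ± 0.22, adjusted p 0.0448) fell in the authors' deposited table. FDPS, which makes a precursor of cholesterol, rose by 0.47 ± 0.13 (adjusted p 0.0421) in the authors' deposited table, a call that was lost after centring.

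Lists shifted by small amounts in the long-form knockout, with almost no member called by the authors' DESeq2 fit, in which 1545 genes of the table had an unadjusted p under 0.05. The cameraPR p-values compare a list's genes with other genes and do not measure how far its change varies between the 2 clones. DNA replication and G1/S genes had 0 of 39 called (0 adjusted over the list alone), with a median of 0.39 (adjusted p 1.19e-09). Mitotic genes (0 of 40, 0 adjusted over the list alone, median 0.23) and repair genes (0 of 28, 1 higher adjusted over the list alone, median 0.23) each had an adjusted p of 0.000331. Complex I had 1 of 35 higher and 0 lower (2 and 0 adjusted over the list alone; median 0.13, adjusted p 0.000119), NDUFS5, at 0.40 ± 0.09 (adjusted p 0.00654) in the authors' deposited table. The mitochondrial ribosome (0 of 78 called, median 0.14, adjusted p 0.000331), ATP synthase (0 of 16, median 0.14, adjusted p 0.00086) and proteasome (0 of 31, median 0.15, adjusted p 0.00086) lists shifted up. So did the aminoacyl-tRNA synthetases (0 of 20, median 0.26, adjusted p 0.0106), complexes II to IV (0 of 25, median 0.12, adjusted p 0.0128) and glycolysis (0 of 29, median 0.19, adjusted p 0.0253) lists. Adjusted over the list alone, 1 ATP synthase gene passed and 0 genes of those other lists. Histone genes had 0 of 6 called (2 lower adjusted over the list alone) and a median of -0.99 (adjusted p 0.000743). With an inter-gene correlation of 0.05, 7 of the 11 lists stayed called, and the mitochondrial ribosome (0.0538), synthetase (0.073), complexes II to IV (0.0992) and glycolysis (0.163) lists did not. Log2 fold changes in cameraPR ended the calls of those 4 lists (0.143, 0.143, 0.319 and 0.229). They also ended those of complex I (0.229), the ATP synthase (0.321) and the proteasome (0.229). Glycolysis was lost with the chromosomal neighbours removed too (0.0635). Against matched random lists the calls of complex I (0.237), the ATP synthase (0.399), the proteasome (0.273), complexes II to IV (0.619) and glycolysis (0.0805) were lost. The p53 targets (0 of 23, median -0.03, adjusted p 0.817) and cytosolic ribosomal proteins (0 of 77, median -0.06, adjusted p 0.176) were not called. The ribosomal protein median did lie below all 10000 matched random lists (adjusted p 0.0022), and the rank-based cameraPR called the list.

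Between the cell lines, 12643 genes had values in both total-knockout tables and 483 were called in both, 414 in the same direction and 69 in opposite directions. Lists drawn independently would share 97.4 genes higher and 107 lower, against 152 (Fisher's exact p 2.92e-09) and 262 (p 2.40e-49) observed. Spearman's rho of the fold changes was 0.25 across 12637 genes, which are not independent replicates. USP11, NEK9 and RMND5B were among those lower in both lines. In UM-UC-3, NEK9 stood at -1.59 ± 0.22 (adjusted p 4.67e-11) and RMND5B at -1.34 ± 0.18 (adjusted p 4.01e-11) in the authors' deposited table. The deubiquitinase STAMBP changed by -2.06 ± 0.29 in A-375 (adjusted p 1.23e-09) and -1.11 ± 0.16 in UM-UC-3 (adjusted p 1.55e-10) in the authors' deposited table for each line. ICA1 (-3.69 ± 0.40 and -2.92 ± 0.45, larger adjusted p 7.56e-09) and the cullin CUL7 (-1.58 ± 0.25 and -1.65 ± 0.25, larger adjusted p 6.28e-08) were lower in the authors' deposited table for A-375 and UM-UC-3, as was the centrosome protein NEDD1 (-1.38 ± 0.21 and -1.11 ± 0.19, larger adjusted p 1.58e-07). Higher in the authors' deposited table for A-375 and UM-UC-3 were the mitochondrial protein FUNDC2 (0.98 ± 0.15 and 0.85 ± 0.10, larger adjusted p 4.86e-08), the growth regulator NOV (3.62 ± 0.63 and 3.75 ± 0.75, larger adjusted p 1.12e-05) and the lysosomal sulfatase IDS (1.43 ± 0.28 and 0.79 ± 0.15, larger adjusted p 4.19e-05).

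**Figure D3:**
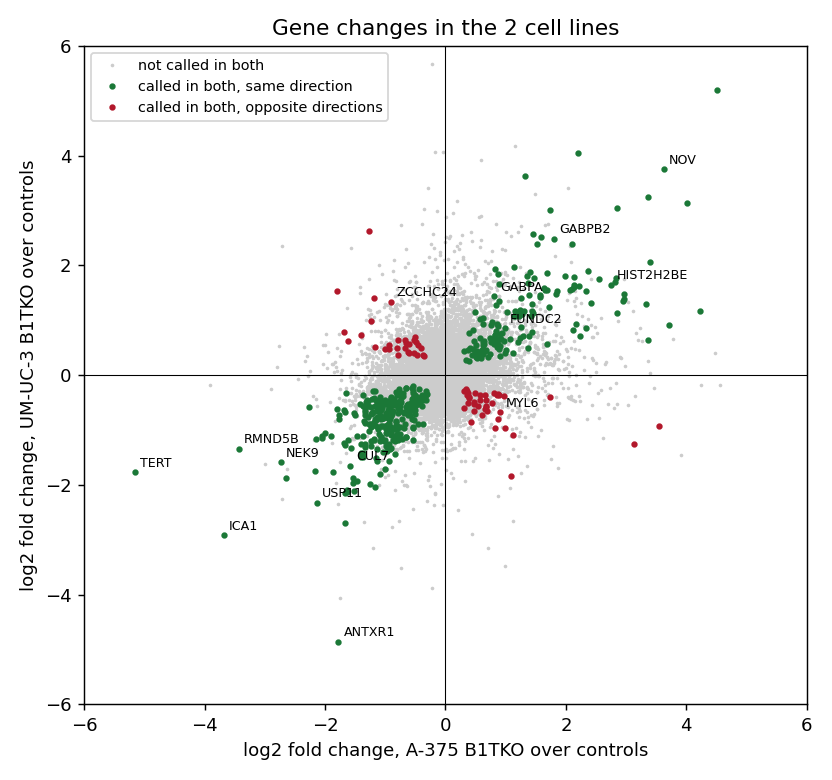
Log2 fold change of each gene in the UM-UC-3 total knockout against that in the A-375 total knockout, both from the authors' deposited tables. Green points were called in both lines in the same direction (414 genes, of which the 4 GABPB1 forms lie outside the plotted range). Red points were called in opposite directions (69 genes) and grey points were not called in both. In all, 18 genes with an absolute log2 change of 6 or more or a mean count under 10 in either line are not shown.

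The difference between the lines was tested for 12640 genes, and 1320 passed, with the A-375 change higher in 521 and lower in 799; after centring both tables the split was 763 and 566. The myosin light chain MYL6 stood at 0.91 ± 0.16 (adjusted p 2.27e-06) in A-375 and -0.68 ± 0.14 (adjusted p 2.84e-05) in UM-UC-3 in the authors' deposited table for each line. Its difference was 1.59 ± 0.21 (adjusted p 7.92e-10). CD163L1 (difference 4.43 ± 0.65, adjusted p 5.10e-08), GALNT18 (2.14 ± 0.32, adjusted p 1.00e-07) and the tRNA-splicing subunit TSEN34 (4.47 ± 0.73, adjusted p 1.11e-06) had the higher change in A-375. ANTXR1 fell in both lines and by more in UM-UC-3 (difference 3.08 ± 0.46, adjusted p 5.58e-08). ZCCHC24 (difference -2.24 ± 0.32, adjusted p 2.93e-08), the chaperone DNAJC12 (-5.89 ± 0.93, adjusted p 5.38e-07) and the adhesion protein NCAM2 (-2.27 ± 0.37, adjusted p 1.36e-06) had the lower change in A-375. For GABPA (-0.62 ± 0.29, adjusted p 0.147), GABPB2 (-0.68 ± 0.38, adjusted p 0.244) and TERT (-3.39 ± 1.81, adjusted p 0.218) a difference between the lines was not shown.

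Of the gene lists, 11 differed between the lines by cameraPR, each with the higher change in A-375. Against matched random lists 14 differed, 12 higher and 2 lower in A-375, the lower ones being mitosis (-0.60, adjusted p 0.00066) and chaperones of the endoplasmic reticulum (-0.38, adjusted p 0.0022). The median difference was 0.61 for cytosolic ribosomal proteins (adjusted p 6.50e-20), 0.49 for the proteasome (1.06e-11), 0.56 for complex I (2.64e-11), 0.56 for complexes II to IV (8.13e-09) and 0.54 for the ATP synthase (2.93e-08). It was 0.70 for p53 targets (1.39e-06), 0.92 for the NF-kB list (0.0027), 0.23 for the mitochondrial ribosome (0.000145), 1.49 for histones (0.000243), 0.46 for glycolysis (0.0181) and 0.25 for replication genes (0.0279). With the trend on transcript length removed, the mitochondrial ribosome (0.288) and histone (0.223) differences were lost, and with that on GC content the glycolysis (0.0876) and replication (0.0616) ones.

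**Figure D4:**
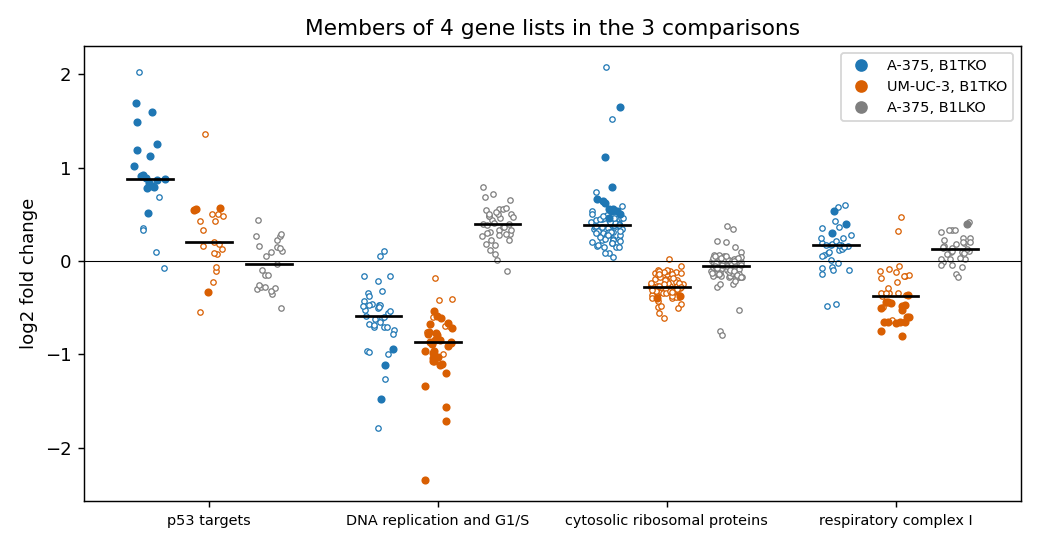
Log2 fold change of each member of 4 gene lists (p53 targets, DNA replication and G1/S, cytosolic ribosomal proteins, respiratory complex I) in the 3 comparisons; each point is a gene, filled where called at an adjusted p of 0.05, and the black line is the list's median. The ribosomal protein medians are 0.39 in the A-375 total knockout, -0.06 in the long-form knockout and -0.27 in UM-UC-3.

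Within A-375, the long-form knockout was set against the total knockout. This asks which changes need the loss of both forms only if the long-form knockout kept the short form, which is not shown. Of 13951 genes in both tables, 28 were called in both, 19 in the same direction and 9 in opposite directions. These 9 include GABPB1S, whose name does not mark the same entry in both tables, and GABPB1S-DEX2. Genes lower in both numbered 16, against 5.31 for independent lists (Fisher's exact p 6.52e-05), and genes higher in both 3, against 1.44 (p 0.173). The 16 include GABPB1L, which both deletions target. They also include FLG, FLG-AS1, HRNR and FLG2, which share a locus, so they are not 16 independent falls. PRPF8 (-1.12 ± 0.32, adjusted p 0.00898), MYO15B (-2.62 ± 0.39, adjusted p 1.49e-08), HRNR (-1.65 ± 0.41, adjusted p 0.0022) and FLG2 (-2.60 ± 0.58, adjusted p 0.000485) were among the shared falls, with these values for the total knockout in the authors' deposited table. If both fits used the same controls, unchanged genes alone would give the Wald statistics a correlation of 0.655 (2 control libraries) or 0.408 (6). The observed one was 0.051 across genes, which are not independent replicates. The observed covariance was 0.113 and the simulated one 0.656 (2) or 0.408 (6), a difference of -0.543 or -0.295. The same sign was seen in 50.2% of genes, against 72.8% (2) or 63.4% (6) simulated, and no simulation gave a gene called in both tables (highest count 0). The observed correlation, covariance and share of the same sign thus all lay below what shared controls would give unchanged genes. Real effects were not simulated and the controls could not be split without values per library. Shared controls were therefore not excluded as a source of part of the excess in the overlap of calls.

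The change differed between these A-375 knockouts in 621 of 13947 genes, with the long-form knockout higher in 371 and lower in 250; after centring, 239 and 287. GABPB2 (difference -1.51 ± 0.42, adjusted p 0.0163) and TERT (5.26 ± 1.71, adjusted p 0.0489) differed, and GABPA (-0.53 ± 0.28, adjusted p 0.272) did not pass. RMND5B (3.16 ± 0.35, adjusted p 2.23e-15), EMILIN2 (4.12 ± 0.47, adjusted p 1.07e-14), NEK9 (2.48 ± 0.32, adjusted p 9.84e-12) and ICA1 (3.88 ± 0.50, adjusted p 1.78e-11), all lower in the total knockout, were not called in the long-form knockout. The phosphodiesterase PDE2A (-5.07 ± 0.76, adjusted p 3.98e-08), HIST2H2BE (-4.15 ± 0.64, adjusted p 1.54e-07), CD163L1 (-5.49 ± 0.86, adjusted p 1.87e-07) and HIST3H2A (-2.58 ± 0.41, adjusted p 2.30e-07) had the lower change in the long-form knockout. By lists, 14 differed. The long-form knockout was lower for ribosomal proteins (median difference -0.43, adjusted p 1.27e-15), histones (-3.74, 2.95e-11), p53 targets (-0.91, 5.95e-11), antigen presentation (-0.88, 4.03e-06), autophagy (-0.36, 4.12e-05) and NF-kB genes (-0.91, 0.000155). It was also lower for GABP subunits (-1.02, 0.0187), blood cell markers (-1.34, 0.0314) and chaperones of the endoplasmic reticulum (-0.17, 0.0351), of which the GABP subunits (0.0730) and the chaperones (0.0546) lost their calls against matched random lists. It was higher for replication (1.01, 1.09e-09), repair (0.95, 1.34e-08), mitosis (1.20, 4.81e-08), telomere (0.38, 0.00876) and aminoacyl-tRNA synthetase (0.45, 0.0187) genes.

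The number of genes called rested on the standard normal null: with each Wald statistic divided by its table's robust SD (1.70, 1.28 and 2.37 in the A-375 total, A-375 long-form and UM-UC-3 tables), 16, 11 and 12 genes passed. This SD was taken over changed and unchanged genes alike, so dividing by it also removes real changes. These are therefore not counts of the reliable changes.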

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

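The tests of list differences with cameraPR, of the p53 list in the long-form knockout and of an exchange of short-form names were chosen only after the result was seen. The results here stood out because the change in the A-375 total knockout differed from that in the UM-UC-3 total knockout by a test of the difference itself. Over all genes 1320 of 12640 differed, and so did 11 gene lists. Of 125 named genes tested, 38 differed, a share raised by the naming rule, which took in genes with the smallest adjusted p for this difference.

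Differences of genes are given as the A-375 minus the UM-UC-3 log2 fold change. Genes called higher in A-375 with a lower change in UM-UC-3, of either sign, were CD163L1 (4.43), HYDIN (3.05), FHL2 (1.54), GALNT18 (2.14), MYL6 (1.59) and, among p53 targets, CDKN1A (1.36), DDB2 (1.34), PLK3 (1.09) and FDXR (0.99). Among ribosomal, respiratory and proteasome genes the difference was 1.40 for RPS21, 1.38 for RPS27, 1.00 for NDUFC2, 0.70 for NDUFB6, 0.82 for NDUFS5, 0.91 for NDUFV2, 1.15 for UQCRQ, 0.81 for COX6A1, 0.86 for MRPL16, 0.82 for MRPL33, 0.70 for PSMC2 and 0.94 for PSMB1. ANTXR1 fell in both lines and by less in A-375 (3.08), and TSEN34, which was not called in A-375, fell in UM-UC-3 (4.47). RMND5B (-2.09), NEK9 (-1.15), STAMBP (-0.95) and MAP2K5 (-0.99) had the lower change in A-375. So had WIPI1 (-1.55), ALDH6A1 (-1.18), GREB1 (-2.88), ZCCHC24 (-2.24), DNAJC12 (-5.89) and NCAM2 (-2.27). Stress genes with the lower change in A-375 were DNAJB9 (-1.33), HSPA5 (-1.04), SEL1L (-0.81) and DDIT3 (-1.60), and LRPPRC differed by -0.57.

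The lists that differed had medians of the A-375 minus UM-UC-3 change of 0.613 for cytosolic ribosomal proteins, 0.559 for complex I, 0.560 for complexes II to IV, 0.538 for the ATP synthase, 0.233 for the mitochondrial ribosome and 0.486 for the proteasome. The others were p53 targets (0.698), DNA replication and G1/S genes (0.247), NF-kB genes (0.922), hypoxia and glycolysis genes (0.462) and histones (1.49).

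The changes of ribosomal protein and respiratory genes differed between the cell lines as lists: 13 of 77 ribosomal proteins were called higher in A-375, and 17 of 37 complex I, 13 of 25 complex II to IV and 12 of 16 ATP synthase genes were called lower in UM-UC-3. With the length trend removed, the ribosomal protein call in UM-UC-3 ended (median from -0.274 to -0.0948, adjusted p 0.147). So did those of complex I (from 0.167 to 0.0377, adjusted p 0.250) and complexes II to IV (from 0.162 to 0.0887, adjusted p 0.268) in A-375, since the medians came nearer to 0. The ATP synthase was not called in A-375 (adjusted p 0.0854), but passed with the chromosomal neighbours removed (0.0264) and with ranks in cameraPR. A bias with transcript length as the whole source is argued against: with that trend removed, the ribosomal protein difference was 0.418 (adjusted p 9.35e-09) against 0.613 before. The differences of complex I and complexes II to IV shrank further, from 0.559 to 0.299 (adjusted p 2.65e-05) and from 0.560 to 0.339 (adjusted p 0.000123), so length goes with part of them. For the ribosomal protein list, a bias with GC content is argued against by a difference of 0.681 (adjusted p 3.02e-18) with that trend removed. High expression alone is argued against for this list, since 0.613 lies above the 0.419 that was the highest of 10000 random lists matched on mean normalized count. Complex I (0.559, highest 0.308) and complexes II to IV (0.560, highest 0.443) also lay above the highest of their random lists. The ATP synthase (0.538) lay below its highest (0.566), with an adjusted p of 0.0022 against these lists. Clones, culture and batch stay open, since each line has its own libraries and the UM-UC-3 table may rest on 1 parental library, and a difference in biology between the lines stays an untested explanation that these values are consistent with.

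The p53 targets rose in the A-375 total knockout (median 0.876) and this rise was larger than in UM-UC-3. A response to Cas9 editing and cloning as such is argued against by the A-375 long-form clones, edited and cloned too, where the median was -0.0295 (adjusted p of the difference 5.95e-11). The histone list, fixed as a check on polyadenylation, differed between these knockouts as well (-3.74, cameraPR adjusted p 2.95e-11). Whether RNA capture differed between these libraries was not tested. Regional dosage in the clones is argued against, since the median was 0.948 (adjusted p 5.95e-16) after each gene's chromosomal neighbours were removed, and transcript length by a median of 0.953 (adjusted p 5.03e-15) with that trend removed. A candidate explanation is that the GABPB1 deletions of the total knockout, in which GABPB1L-DEX2 and GABPB1S-DEX2 RNA remained, activate p53 in A-375. It stays a hypothesis, because the number of long-form libraries was small and it was found and tested on the same data. Culture or batch differences between the A-375 knockouts could not be tested. Whether the long-form knockout kept the short form is also not shown. GABPB1S-DEX2, the short-form entry of its controls, fell to near 0, while an entry named GABPB1S rose from near 0.

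The short forms of GABPB1 went opposite ways in the A-375 tables, GABPB1S down in the total knockout and up in the long-form knockout, and GABPB1S-DEX2 the reverse. If the names of the short forms were exchanged between the tables, the control level of GABPB1S in the first would match that of GABPB1S-DEX2 in the other. The ratio was 1.69 with 2 control libraries assumed and 1.09 with 6, and GABPB1L, whose name needs no exchange, gave 1.69 and 1.09 as well. The control levels of the 2 short-form entries thus matched as closely as those of GABPB1L with either number of controls. All these levels lay closer between the A-375 fits with 6 controls than with 2. So did those of TERT (537 total, 561 long-form with 6, 1132 and 551 with 2). Those of GABPB2 lay closer with 2 (346 and 347, against 407 and 365 with 6), as did those of GABPA. The genes that fell most thus go with 6 controls, ROSA26 clones included, without settling it. UM-UC-3 has 1 fit only and could not be compared in this way. An exchange of names and a different definition of the entries cannot be told apart, because the definitions of the entries are not given in the sources used here. No biological explanation was tested.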

How the results depend on the processing

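The q-value, the removal of trends on length and GC content, the removal of 50 chromosomal neighbours and the tests of list differences were chosen only after the data were seen. No paired analysis was possible because the tables hold 1 value per gene for a whole fit and the columns carry no replicate numbers. For the same reason leave-one-out fits, a replicate block, other splits of the samples and an estimated inter-gene correlation were not run. The depth per library is unknown, so what depth limits cannot be stated beyond the standard errors.

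Counts of called genes moved with the strictness of the test by its construction. In the A-375 total knockout the count of 1549 became 705 at an adjusted p of 0.01, 2397 at 0.1, 726 with a log2 change of at least 1 and 121 in a test against a log2 change of 0.5. In the A-375 long-form knockout 128 became 62 at 0.01, 74 with a change of at least 1 and 12 against 0.5. In UM-UC-3 4145 became 2710, 895 and 328 in these settings. With Wald statistics divided by their robust SD, 16, 11 and 12 genes were left in the 3 tables. That SD includes real changes, and the cause of the wide statistics was not tested. A floor on the mean count, adjustment over all genes with a p, and the q-value (2175, 136 and 5511 genes) moved no count by over 1.5 times. Centring moved the share higher in the A-375 total knockout from 46.9% to 58.4% (907 higher, 647 lower).

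Genes whose change differed between the lines numbered 518 at an adjusted p of 0.01 and 642 with a difference of at least 1, against 1320. Centring turned 521 higher and 799 lower in A-375 into 763 and 566. Between the A-375 knockouts 621 became 186 at 0.01 and 396 with a difference of at least 1. It became 4465 or 2265 with the covariance of 2 or 6 shared controls removed, values that hold only if controls were shared, and the covariance observed (0.113) was below that of shared controls. Centring turned 371 higher and 250 lower into 239 and 287. Genes called the same way in both lines numbered 159 at 0.01 and 125 with a change of at least 1 in both, against 414. In the A-375 knockouts 19 became 9 at 0.01.

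Of gene lists, the long-form knockout kept 4 of 11 calls with log2 fold changes in place of Wald statistics and 7 with an inter-gene correlation of 0.05; the cause was not tested for the first, and the second follows from its wider error. Numbers of called lists ranged from 11 to 18 over all alternatives in the A-375 total knockout, 4 to 13 in the long-form knockout and 12 to 18 in UM-UC-3. They ranged from 9 to 14 for the difference between the lines and 14 to 15 within A-375, over 3 alternatives only (length, GC content, random lists); an inter-gene correlation of 0.05, log2 fold changes and ranks were not run on list differences. Of list calls under each alternative, 121 stayed and 14 were lost in the A-375 total knockout, 82 and 17 in the long-form knockout, 136 and 17 in UM-UC-3, 29 and 4 between the lines, and 40 and 2 within A-375. Of named genes centred on the median, 387 values kept their side of the threshold, 5 lost a call and 3 gained one, and none reversed.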

Other observations

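The motif count in the long-form knockout was chosen only after the result was seen; the other tests of hypotheses in this part were set down before. Genes lower in both total knockouts carried an ETS site at their start more often. Among 257 genes lower in both cell lines, 60 (23.3%) had CCGGAAG or its reverse complement in the first 100 nt of an annotated transcript, against 1140 of 12106 other genes (9.42%; one-sided Fisher's exact p 6.96e-11, over genes, which are not independent replicates). Among 149 genes higher in both lines it was 11 (7.38%), against 9.73% of the others (p 0.867). Part of the shared falls may thus follow directly from the loss of GABP at such sites, a hypothesis that the values for the genes lower in both lines are consistent with. A site read by another ETS factor would give the same share, and no binding data were used here. The other genes were not matched on expression, GC content or promoter type, so a share that follows from these was not tested. In the A-375 long-form knockout, 4 of 84 lower genes (4.76%) had the motif, against 9.11% of the others (p 0.954).

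The epidermal genes FLG, HRNR and FLG2, which lie next to each other on chromosome 1, fell in both A-375 knockouts. FLG-AS1, which spans them on the opposite strand, fell too (-1.54 in the long-form and -2.91 in the total knockout). Whether the counting used the strand is not given, so these falls may come from shared reads. A shift of the whole region is argued against: the other genes within 1 Mb of FLG had a median log2 change of 0.196 in the long-form knockout (16 genes) and 0.05 in the total knockout (19 genes). A shared control that happened to be high for these genes was not tested, since no value per library was used here.

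Neighbouring genes moved together. The SD over windows of 50 neighbouring genes of their median log2 change was 0.126 in the A-375 total knockout, 0.0878 in the long-form knockout and 0.116 in UM-UC-3, against at most 0.0862, 0.0537 and 0.0873 in 200 shuffles of gene order. Gains or losses of chromosome segments in single clones are a candidate explanation, and shared regulation of neighbours would give the same. The lowest window in the A-375 total knockout lay on chromosome 13 (43879284 to 52643796, median -0.54) and the highest on chromosome 6 (30876421 to 33323016, median 0.44), which holds HLA-B. In the long-form knockout the extremes were on chromosome 9 (133459965 to 137086817, -0.35) and chromosome 3 (41246599 to 48301685, 0.25), and in UM-UC-3 on chromosome 12 (280129 to 6889358, -0.27) and chromosome 14 (35044907 to 50668331, 0.35).

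The list of GABP subunits without GABPB1 was called higher in both total knockouts (median 1.31, adjusted p 0.000539 in A-375; 1.96, 2.70e-07 in UM-UC-3) and not in the long-form knockout (0.29, 0.208). CD68 rose in A-375 as well, by 1.43 ± 0.34 (adjusted p 0.00111) in the authors' deposited table, and the blood cell markers were not called there as a list (adjusted p 0.0713).

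Lists not called in the A-375 total knockout, with their adjusted p, were ETS factors (0.871), ATP synthase (0.0854), mitochondrial ribosome (0.934), mitochondrial DNA expression (0.562), aminoacyl-tRNA synthetases (0.269), the ATF4 response (0.571), MAPK output (0.753), YAP targets (0.148), hypoxia and glycolysis (0.0860), cholesterol synthesis (0.871), NRF2 targets (0.0654), pigment (0.503), urothelial (0.878), mesenchymal (0.177), neural crest (0.516) and endothelial (0.713) genes. Against matched random lists the neural crest genes were called higher (0.0264). The ATP synthase was called with the chromosomal neighbours removed (0.0264) and with ranks in cameraPR. NRF2 targets were called with ranks and with a mean count of at least 100. Median, mean and test differed in sign for ETS factors (median -0.05, mean 0.08, test down), MAPK output (-0.01, 0.08, up), cholesterol synthesis (-0.02, -0.08, up), urothelial (-0.13, 0.09, up) and neural crest genes (0.33, -0.02, up).

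In UM-UC-3, the lists not called were ETS factors (0.270), telomere maintenance (0.144), antigen presentation (0.0884), NF-kB (0.574), MAPK output (0.270), YAP targets (0.326), hypoxia and glycolysis (0.281), cholesterol synthesis (0.281), NRF2 targets (0.326), pigment (0.281), urothelial (0.339), mesenchymal (0.638), neural crest (0.841) and endothelial (0.815) genes, besides the p53 and ATF4 lists. Against matched random lists, antigen presentation (0.0111), MAPK output (0.0030) and pigment (0.0101) genes were called higher, and antigen presentation also with the length trend removed (0.0314). With log2 fold changes in cameraPR, antigen presentation and pigment genes were called. The ATF4 list had a median of 0.04, a mean of 0.11 and a test pointing down.

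In the long-form knockout, the lists not called were ETS factors (0.0739), telomere maintenance (0.0989), mitochondrial DNA expression (0.0739), the ATF4 response (0.193), chaperones of the endoplasmic reticulum (0.380), interferon-stimulated genes (0.178), antigen presentation (0.463), NF-kB (0.207), MAPK output (0.248), YAP targets (0.907), cholesterol synthesis (0.442), autophagy (0.817), NRF2 targets (0.186), pigment (0.463), urothelial (0.612), mesenchymal (0.907), neural crest (0.817), blood (0.187) and endothelial (0.992) genes. Against matched random lists interferon-stimulated genes were called higher (0.0183) and MAPK output lower (0.0170). Median, mean and test differed in sign for cholesterol synthesis (0.05, -0.0036, up), neural crest (-0.11, -0.01, up) and endothelial genes (-0.04, -0.09, up).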
